A study of Mus musculus with 21 samples.

How the data were processed

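The deposited files hold a table of RMA values for 21 Affymetrix Mouse Gene 1.0 ST arrays and 4 tables of changed genes. Per the labels, each array was hybridized with RNA from flow-sorted CD4 CD8 double-positive thymocytes of C57 Bl/6 mice. The values of the table are log2 RMA signals per probe set, which the authors made, per the labels, with RMA in Affymetrix Expression Console. The series design text states that arrays were normalized in groups that follow the binary comparisons. In the authors' tables the fold change is a ratio of treated over control, the score is the d score of the SAM package, and the q value is given in percent; the readme deposited with the tables is the source for SAM. The authors' folds matched the deposited columns in the knockout and VP16 comparisons (r = 1.0000 over 2301 rows) and were close but not equal in the OT-2 (r = 0.982, median absolute difference 0.06 in log2) and peptide comparisons (r = 0.950, 0.09). The deposited columns, grouped as here, thus do not give those folds, and the reason was not tested. Versions of RMA, Expression Console and SAM are not given in the sources used here.

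The columns were checked for shared scale before use. They fell into 4 blocks: wild-type arrays 1 to 3, knockout and peptide-injected OT-2 (9 arrays, 3 decimals, medians from 6.15 to 6.26 and SD from 2.14 to 2.22), wild-type arrays 4 to 6 and VP16 (6 arrays, 6 decimals, medians 6.01 to 6.09, SD 2.38 to 2.42), OT-2 (3 arrays, medians 6.18 to 6.21, SD 2.23 to 2.26) and deltaP (3 arrays, 2 decimals, medians 6.02 to 6.07, SD 2.26). Groups were taken from the sample titles: wild type 6, and 3 each of knockout, VP16, OT-2, peptide-injected OT-2 and peptide-injected OT-2 deltaP, the last of which carries only the OT-2 tag in its genotype label. Following the design text, knockout was compared with wild-type arrays 1 to 3, VP16 with wild-type arrays 4 to 6, OT-2 with all 6, and peptide-injected OT-2 with OT-2. The deltaP arrays, which the design text does not mention, were compared with peptide-injected OT-2 and, as a secondary comparison, with OT-2. The difference between the VP16 and knockout effects and the difference between the wild-type sets were tested as well.

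The value table has 35556 rows. Of these, 6612 in the block numbered below 10344614 were left out as control rows, since 0 of the 2301 rows of the authors' tables lay there where 428 would by chance. Of the 28944 others, 23 second probe sets of a named gene were dropped (the probe set with the highest mean was used), and 28921 were tested. No probe annotation came with the files, so genes were named only through the authors' tables: 2144 rows had 1 symbol (1926 through an accession, 118 through a current symbol, 63 through a synonym and 37 with the symbol of the file), 156 had none and 1 had several. In all 2121 tested rows were named and 26800 were not, so that every gene named was one the authors had listed in at least 1 comparison. The 26 gene lists were fixed before the data were examined, with 450 genes of which 186 were named here; 20 lists had 3 or more members and were tested.

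Each comparison was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on its own arrays only, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A gene changed when its adjusted p was under the threshold. Lists were tested with camera at a preset correlation of 0.01 with the named rows as the background, adjusted over the lists of a comparison, and again with the correlation estimated per list and with fry. Beside the count over all genes, members were counted when adjusted over the list alone; because the authors chose the named genes on these samples, that count is not independent evidence. Changes of different comparisons were correlated across genes, with a jackknife over arrays for the error, and pairs that share arrays were set beside unchanged groups simulated on the same arrays. Genes called in the one comparison were tested as a set in the other with camera, 14 tests in all. Tables and figures were made in python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

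Genes named in the text followed a rule fixed before the data were examined: Hdac7; the 8 largest rises and the 8 largest falls among changed genes whose arrays do not overlap and whose higher mean lies above the median; up to 4 members with the smallest adjusted p from each list, or up to 2 with the largest change where none passed; and up to 10 shared genes per pair of comparisons. T cell receptor segments and unnamed genes were counted but not named. Some genes that this rule chose are not reported here. Cd6 and Ms4a6b in the knockout, Hdac5 in VP16, Ifngr1 after peptide, and the genes given for deltaP against OT-2 and the unnamed probe sets with either high or low values were named after their values were seen. Whether replicate numbers pair arrays was checked by correlating deviations from the group mean. Knockout and wild-type arrays of the same number correlated at 0.424, 0.261 and 0.250, with 0.0009 as the highest for other combinations, so these numbers were taken to pair. In the group pairs taken as unpaired, arrays of different numbers reached 0.276, so the lower values alone do not show pairing. The knockout's values per gene and list come from the fit without pairs. Blocked values are given for the counts and for the maturation list, whose call the block ended. Numbers did not pair the arrays elsewhere. No paired analysis was possible for VP16 because its replicate numbers 1 to 3 are not shared with wild-type arrays 4 to 6.

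Alternatives fixed before the data were examined were all 21 arrays in 1 fit, quantile normalization of all 21 arrays, arrays centred on their medians, genes above the median level, an added threshold of 1.5-fold, an intensity trend with robust fitting, array weights, every row of the value table, the replicate block, other wild-type controls, and leaving out each array. Removing the difference between the wild-type sets from every array, treating these sets as 2 groups in the OT-2 comparison, the replicate block for the difference between the VP16 and knockout effects, and the other scalings of deltaP against OT-2 and of the wild-type sets were chosen after seeing the data. The pipeline was tested on simulated data: of 100 genes changed 2-fold in arrays like those of each comparison, 79 were recovered for the knockout, 91 for VP16, 69 for OT-2, 81 for peptide and 79 for deltaP, and 97 or more of 100 changed 4-fold. False calls made up 3.74% to 6.67% of the calls. The simulated noise was independent between genes and held no block difference. This share therefore does not carry over to the real calls, least of all where a comparison crosses blocks.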

Results

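Gene expression was measured on 21 Affymetrix Mouse Gene 1.0 ST arrays, each hybridized with RNA from flow-sorted thymocytes that carried both CD4 and CD8, the double-positive stage at which the T cell receptor is tested. The design text calls the samples biological replicates. Wild-type mice gave 6 arrays, and 3 arrays came from each of 5 other groups: mice lacking histone deacetylase 7 (HDAC7), mice carrying HDAC7 fused to the VP16 activator, mice with the OT-2 T cell receptor transgene, OT-2 mice injected with agonist peptide 3 hours before harvest, and peptide-injected OT-2 mice with an HDAC7 deltaP transgene. The number of arrays limits the precision of every value. All changes are differences of mean log2 RMA signal with the standard error of the limma fit. Arrays of one group correlated at r from 0.987 to 0.997 across genes. The deposited columns fall into 4 blocks with their own decimals and distributions, and wild-type arrays 1 to 3 and 4 to 6, which lie in different blocks, differed in 16468 genes. The knockout and VP16 comparisons each lie inside a block, whereas the peptide and deltaP comparisons each set one block against another, and the OT-2 arrays form a block apart from both wild-type sets, so that for these 3 comparisons block and group cannot be told apart. Only genes in the authors' own tables of changed genes carry names here, 2121 of the 28921 rows tested, and the members of each gene list are therefore those the authors listed on these samples, which is not independent evidence.

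**Figure D1:**
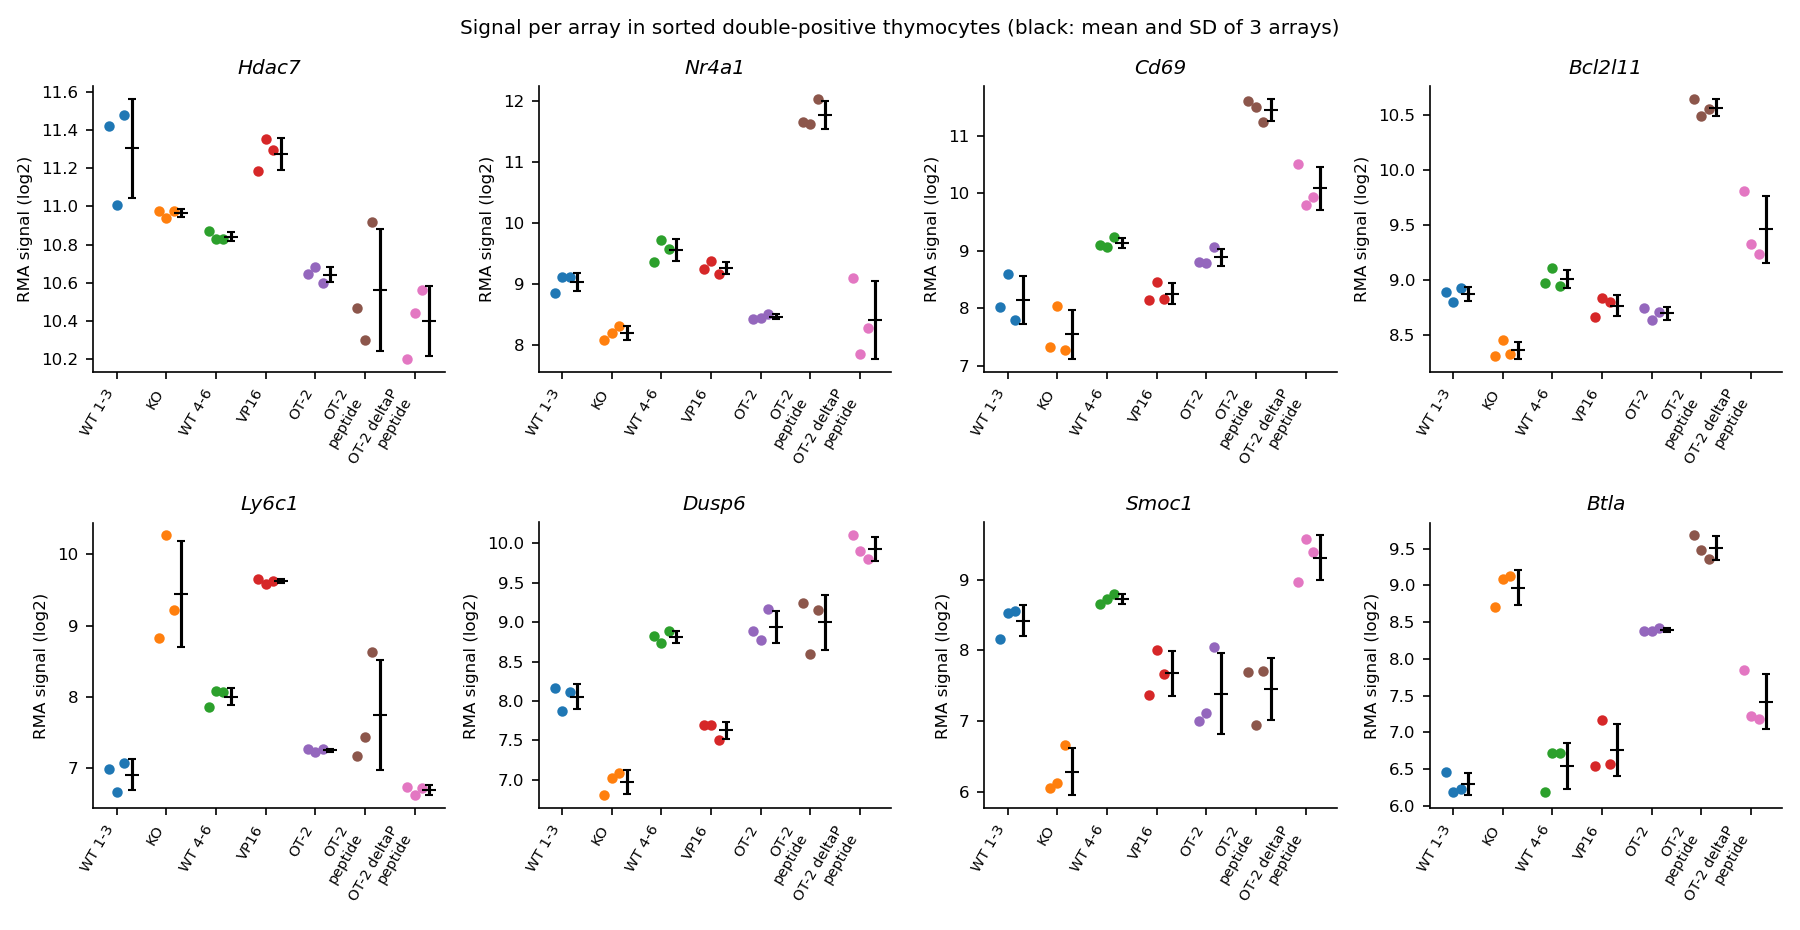
Each point is the RMA signal (log2) of 1 array for 8 genes, with the wild-type arrays in the sets 1 to 3 and 4 to 6; black marks give the mean and SD of 3 arrays. Nr4a1 had a mean of 11.77 in the peptide-injected OT-2 arrays against 8.47 in the OT-2 arrays and 8.41 in the deltaP arrays.

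The Hdac7 probe set read from 10.94 to 10.98 in the 3 knockout arrays and from 11.01 to 11.48 in wild-type arrays 1 to 3, a change of -0.34 ± 0.14 (adjusted p = 0.664) that did not pass. No table gives the positions of its probes or of the deleted part, so the absence of HDAC7 rests on the labels. In the VP16 arrays Hdac7 rose by 0.44 ± 0.07 (adjusted p = 0.0353), and passed in 1 of the 6 fits that left out an array. Hdac7 did not pass in OT-2 (-0.43 ± 0.17, adjusted p = 0.226), after peptide (-0.08 ± 0.15, adjusted p = 0.727; the sign turned to 0.10 after quantile normalization) or with deltaP (-0.16 ± 0.17, adjusted p = 0.517; the sign turned to 0.03 with arrays centred on their medians). Hdac5, which codes for a deacetylase of the same class, rose by 1.25 ± 0.12 in the knockout (adjusted p = 0.0033) and fell by 0.58 with deltaP (adjusted p = 0.0089). Hdac7 and Hdac5 were the named members of the list of histone deacetylases, too few for a list test. In the other comparisons Hdac5 did not pass (VP16 0.50, OT-2 0.43 and peptide 0.04, the last with the sign turned to -0.02 on arrays centred on their medians).

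The comparison of knockout with wild-type arrays 1 to 3 asks what loss of HDAC7, as the labels give it, changes in these cells. Btla, the gene of an inhibitory receptor, rose by 2.68 ± 0.14 (adjusted p = 4.49e-04, n = 3 and 3). Ms4a4b, which codes for a membrane protein of maturing T cells, rose by 2.59 ± 0.18 (adjusted p = 7.87e-04), and P2rx7, the gene of an ATP-gated channel, by 2.13 ± 0.13 (adjusted p = 5.11e-04). Cacna1e, a calcium channel gene, changed by -2.47 ± 0.23 (adjusted p = 0.0027), and Jup, which codes for the junction protein plakoglobin, by -2.33 ± 0.19 (adjusted p = 0.0017). The other large rises were Prm1 (2.85), Ly6a (2.82), Ly6c1 (2.53), Chl1 (2.34) and Dap (2.15), and the other large falls were Xkrx (-2.40), Smoc1 (-2.14), Slc7a11 (-2.04), Slc6a19 (-1.96), Slc28a2b (-1.71) and Scn4b (-1.69). Of the 232 genes that changed, 127 rose and 105 fell, and 293 changed with the replicate number as a block. The values per gene come from the fit without that block. The 36 changed genes selected for naming all passed with it as well, and 25 of them passed whichever array was left out and under both other scalings. Ly6a passed in 2 of those 6 fits, Ly6c1 in 3, Chl1 in 1 and Slc7a11 in 1. With 1 array left out the count was 117 and 118 without knockout replicates 2 and 3 in turn, and 111, 125 and 107 without wild-type replicates 1, 2 and 3 in turn.

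Several genes that respond to T cell receptor signals fell in the knockout. The lists of 22 T cell receptor activation genes and 14 NF-kB targets, of which 3 and 1 fell, did not pass (camera adjusted p = 0.0872 each, adjusted p = 0.534 each with an estimated correlation). Egr1, an immediate-early transcription factor gene, changed by -0.93 ± 0.10 (adjusted p = 0.0061), and Nfkbia, which codes for the inhibitor of NF-kB, by -0.88 ± 0.10 (adjusted p = 0.008). Nr4a1 (-0.83 ± 0.12, adjusted p = 0.0185) and Egr2 (-1.12 ± 0.18, adjusted p = 0.0303) fell too, but passed in 1 and 0 of the 6 fits that left out an array. In the list of 7 MAPK feedback regulators, Dusp4 (-1.25) and Dusp6 (-1.08), the genes of phosphatases that act on ERK kinases, fell and 5 did not pass. All 7 were lower, 5 fell when adjusted over the list alone, and the median was -0.52 (camera adjusted p = 0.0023, adjusted p = 0.692 with an estimated correlation). Of 8 pre-selection genes, Ets2 (-1.49), a transcription factor gene, and Ptcra (-1.11), the gene of the pre-T cell receptor chain, fell, 4 fell when adjusted over the list alone, and the median was -0.47 (adjusted p = 0.0054, adjusted p = 0.534 with an estimated correlation). Bmf, the gene of a pro-apoptotic BH3 protein, fell as well (-1.43 ± 0.13, adjusted p = 0.0027).

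Genes of later maturation rose in part. Of 19 post-selection maturation genes, 5 rose, 0 fell and 14 did not pass. Among the 5 were Ms4a4b (2.59), Ms4a6b (1.48), Cd5 (1.17) and Gata3 (1.12), where Cd5 tunes receptor signals and Gata3 directs the CD4 lineage. The same 5 rose when adjusted over the list alone, and the median was 0.17 (adjusted p = 0.0398, adjusted p = 0.84 with an estimated correlation). The list's adjusted p was 0.0519 with the replicate block and did not pass without knockout replicate 2 (0.262), wild-type replicate 1 (0.117) or wild-type replicate 3 (0.0517), in a range from 0.0011 to 0.262 over the alternatives. The 14 interferon-stimulated genes had a median of 0.41 with 0 that rose, also when adjusted over the list alone (adjusted p = 0.0476, adjusted p = 0.84 with an estimated correlation), and this call was lost without the same 3 arrays (0.298, 0.172 and 0.0562) and after quantile normalization (0.0508), in a range from 0.0018 to 0.298. Of the 22 T cell receptor activation genes, 2 rose, Cd5 and Cd6 (0.69), and 3 fell (adjusted p = 0.0872, adjusted p = 0.534 with an estimated correlation). Stat4 (1.09), a cytokine signal transducer gene, Tgfbr2 (0.94), a growth factor receptor gene, Prkcq (0.69), a receptor-signalling kinase gene, Cd200 (1.36) and Itgam (0.89), an integrin gene of myeloid cells, rose, and Socs1 (-0.97) and Socs3 (-1.18), the genes of cytokine signalling inhibitors, fell. Of these, Stat4, Cd200 and Itgam passed whichever array was left out, Prkcq in 0 of 6 such fits, Tgfbr2 in 1, and Socs1 and Socs3 in 2 each. The 16 lists that did not pass had adjusted p from 0.0872 to 0.9408. Of these, the cell cycle list had all 23 members higher (camera adjusted p = 0.0897, adjusted p = 0.84 with an estimated correlation). It passed without knockout replicate 3 (0.0283) or wild-type replicate 1 (0.0041), as did the receptor activation list (0.0483 and 0.0279). By fry the receptor activation (adjusted p = 0.0159) and NF-kB (adjusted p = 0.0127) lists passed.

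The VP16 comparison, against wild-type arrays 4 to 6, asks what HDAC7 turned into an activator changes. Pcsk1, which codes for a prohormone protease, rose by 2.94 ± 0.17 (adjusted p = 5.61e-04, n = 3 and 3), and Vim, the gene of the filament protein vimentin, by 1.99 ± 0.08 (adjusted p = 1.37e-04). Gzma, which codes for a cytotoxic granule protease, rose by 1.39 ± 0.08 (adjusted p = 5.61e-04), and Ctla4, the gene of an inhibitory receptor, by 1.38 ± 0.10 (adjusted p = 0.0015). Dusp6 changed by -1.19 ± 0.08 (adjusted p = 0.0013). Large rises were also seen in Lyn (1.74), Actn2 (1.71), St3gal6 (1.70), Gfra1 (1.64) and Ly6c1 (1.62). The falls included Dusp4 (-1.28), Smoc1 (-1.05) and Cenpk (-1.02), and Depdc1a (-1.09) and Bub1 (-0.99), the last 2 of which, genes of mitosis, did not pass after quantile normalization. The receptor-response genes that fell were Egr1 (-0.87), Cd69 (-0.89), an early activation marker, Pdcd1 (-0.62) and Nab2 (-0.46), each passing in at most 3 of the 6 fits that left out an array. They belong to the list of 22 T cell receptor activation genes, which did not pass: 4 fell, 1 rose, Il2ra, and 17 did not pass, with 9 higher and 13 lower and a median of -0.08 (adjusted p = 0.64, adjusted p = 0.874 with an estimated correlation). When adjusted over the list alone 8 fell and 4 rose. Among the 40 changed genes selected for naming, 12 passed whichever array was left out and under both other scalings, Pcsk1, Vim, Gzma, Ctla4 and Dusp6 among them.

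The comparison gave 411 changed genes, 200 higher and 211 lower. The split was 135 and 53 after quantile normalization and 184 and 390 with arrays centred on their medians. With 1 array left out the count was 790, 156 and 38 without VP16 replicates 1, 2 and 3 in turn, and 52, 35 and 79 without wild-type replicates 4, 5 and 6 in turn. In these fits the rises and falls numbered 34 and 4 without VP16 replicate 3, and 46 and 6, 34 and 1, and 59 and 20 without wild-type replicates 4, 5 and 6 in turn, so the near-even split did not hold there. With all 6 wild-type arrays as control they were 31 and 3. Of the lists, the cell cycle list alone passed. All 23 members were lower, with a median of -0.82. Ccne2 (-0.91), the gene of cyclin E2, and Bub1 (-0.99), a spindle checkpoint kinase gene, fell over all genes (both did not pass after quantile normalization), 21 did not pass, and 23 fell when adjusted over the list alone (adjusted p = 8.72e-07, adjusted p = 0.869 with an estimated correlation). By fry this call was lost (0.0706), and in the other alternatives the adjusted p ranged from 1.17e-08 to 2.98e-06. The list of 7 MAPK feedback regulators had a median of -0.27, and 4 fell when adjusted over the list alone, but the list did not pass (adjusted p = 0.0607, adjusted p = 0.869 with an estimated correlation; 0.036 after quantile normalization, in a range from 0.0303 to 0.115 over the alternatives). Of 19 maturation genes, 4 rose, Ms4a6b (0.92), Gata3 (0.60) and Itgb7 (1.04) among them, and Cd69 and Cd52 (-0.50; -0.44, adjusted p = 0.0517 after quantile normalization) fell (adjusted p = 0.351, adjusted p = 0.869 with an estimated correlation). Stat4 (0.74) and Ifngr1 (0.39), genes of cytokine signalling, and Blk (1.01), a kinase gene of B and immature T cells, rose. Of 5 double-negative markers 4 were higher, with a median of 0.51, but the list did not pass (adjusted p = 0.296, adjusted p = 0.869 with an estimated correlation). Il2ra (1.18) and Dtx1 (0.69) rose, each in 1 of the 6 fits that left out an array and not after quantile normalization, and 4 rose and 1 fell when adjusted over the list alone. The 19 lists that did not pass had adjusted p from 0.0607 to 0.9977.

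**Figure D2:**
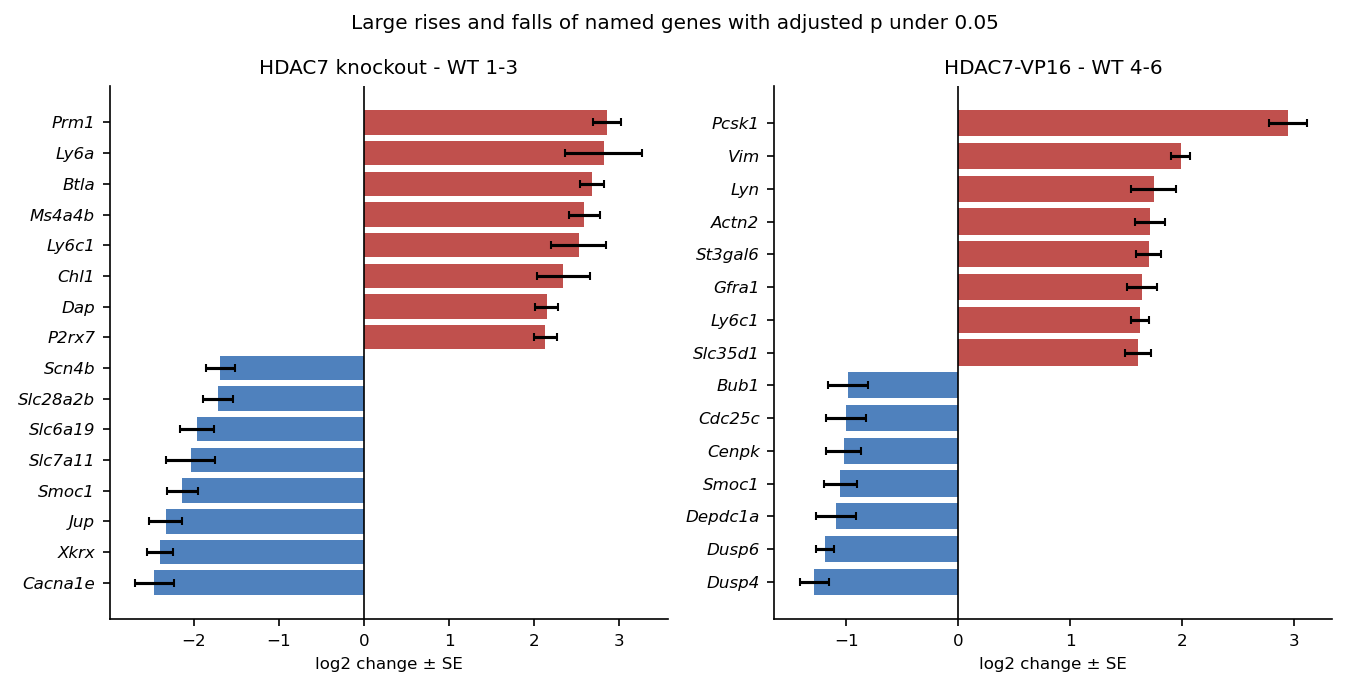
Bars give the log2 change and its SE for named genes with large rises and falls in the knockout (left) and VP16 (right) comparisons, 3 arrays per group. Ly6c1 and Smoc1 appear on both sides with the same sign, and Pcsk1 has the longest bar on the right at 2.94.

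The knockout and VP16 comparisons use different wild-type arrays, so their overlap has no array in common. Genes called up in both numbered 42, where independent lists of these sizes give 0.878, and 11 were called down in both, where 0.766 would be. They included Ly6c1 (2.53 and 1.62), Ly6c2 (2.01 and 1.39), Actn2 (1.78 and 1.71), St3gal6 (1.37 and 1.70), Il18r1 (1.34 and 1.17) and Dusp4 (-1.25 and -1.28), given as the change in the knockout and in VP16. The 127 genes that rose in the knockout had a median of 0.29 in VP16 and 107 of them were higher there (camera adjusted p = 1.28e-27 over 14 such tests, adjusted p = 0.132 with an estimated correlation). The 105 genes that fell in the knockout had a median of -0.05 in VP16, with 40 higher and 65 lower (camera adjusted p = 2.07e-05, adjusted p = 0.286 with an estimated correlation). Across all genes the changes correlated at r = 0.08 (rho = -0.03), and across the named genes at r = 0.22. Genes are not independent replicates, and leaving out arrays in turn gave the first r a standard error of 0.14. The difference between the effects passed for 231 genes, 137 with a higher and 94 with a lower effect in VP16, and for 633 with the replicate number as a block in the knockout pairs, where 278 were higher and 355 lower. The effects had opposite signs in 160 of the 231, and 10 of the 42 genes called up in both differed in size. With 1 array left out the count was 136 without knockout replicate 2, and 399, 124, 123, 97 and 139 without wild-type replicates 1, 3, 4, 5 and 6 in turn, and 104 and 93 without VP16 replicates 2 and 3 in turn.

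The OT-2 comparison, against all 6 wild-type arrays, addresses positive selection per the design text. Il2ra, the gene of the interleukin 2 receptor alpha chain, rose by 2.69 ± 0.26 (adjusted p = 0.0015, n = 3 and 6), and Btla by 1.98 ± 0.15 (adjusted p = 4.34e-04). Ifit1, an interferon-induced gene that restrains viral RNA, rose by 2.02 ± 0.25 (adjusted p = 0.0042), and Socs1 changed by -1.38 ± 0.13 (adjusted p = 0.0013). Tdrd5, which codes for a tudor-domain protein, changed by -1.64 ± 0.13 (adjusted p = 4.34e-04). The remaining large rises were Rtp4 (1.92), Gpr65 (1.79), Ms4a4b (1.78), Trim30d (1.78) and Tgtp1 (1.70), and large falls were also seen in Mir181a-1 (-1.65), Slc6a19 (-1.48), Gramd3 (-1.47) and Cacna1e (-1.41). Among receptor-response genes Nr4a3 fell (-0.92 ± 0.11, adjusted p = 0.0032), and so did Nr4a1 (-0.83 ± 0.18, adjusted p = 0.0433), whose call held in 2 of the 9 fits that left out an array. The list of 22 T cell receptor activation genes did not pass, with 13 higher and 9 lower, 1 risen and 2 fallen (median 0.08, adjusted p = 0.713, adjusted p = 0.969 with an estimated correlation). Of the 38 changed genes selected for naming, 12 passed whichever array was left out and under both other scalings, among them Il2ra, Btla, Ifit1, Irf7, Isg15, Rtp4, Trim30d, Hes1, Socs1, Tdrd5 and Nr4a3. The comparison gave 667 changed genes, 369 higher and 298 lower, and with arrays centred on their medians the split was 279 and 482. With 1 array left out the count was 51, 51 and 198 without OT-2 replicates 1, 2 and 3 in turn, and 315, 344 and 359 without wild-type replicates 4, 5 and 6 in turn.

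Of 14 interferon-stimulated genes, 6 rose and 8 did not pass, among the former Isg15 (1.15) and Irf7 (1.12), an interferon regulatory factor gene. All 14 were higher, 13 rose when adjusted over the list alone, and the median was 0.93 (adjusted p = 1.74e-06, adjusted p = 0.776 with an estimated correlation). Of 19 maturation genes, 4 rose: Ms4a4b, Ccr4 (1.28), a chemokine receptor gene, Zbtb7b (0.76), which codes for the CD4-lineage factor ThPOK, and Tox (0.60), a factor gene needed for CD4 cells. The other 15 did not pass, 11 rose when adjusted over the list alone, and the median was 0.60 (adjusted p = 1.43e-04, adjusted p = 0.902 with an estimated correlation). Of 5 double-negative markers, Il2ra and the Notch pathway genes Hes1 (1.35), Dtx1 (1.67) and Notch3 (0.91) rose, the same 4 when adjusted over the list alone, with a median of 1.35 (adjusted p = 0.0032, adjusted p = 0.204 with an estimated correlation). Of 11 cholesterol synthesis genes, Mvd (0.54) and Fdft1 (0.75) rose, 9 did not pass and 6 rose when adjusted over the list alone, with a median of 0.49 (adjusted p = 0.0032, adjusted p = 0.902 with an estimated correlation). Of 7 heat shock and unfolded protein genes, the chaperone gene Hspa5 (1.46) rose, 6 did not pass and 5 rose when adjusted over the list alone, with a median of 0.54 (adjusted p = 0.0351, adjusted p = 0.902 with an estimated correlation). The heat shock call was lost without OT-2 replicate 1 (0.062) or 2 (0.051), or wild-type replicate 1 (0.0591), in a range from 0.0114 to 0.062. After quantile normalization 12 interferon, 11 maturation, 5 cholesterol synthesis and 4 heat shock genes rose. The 15 lists that did not pass had adjusted p from 0.0841 to 0.9906.

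Set against wild-type arrays 4 to 6, which the knockout comparison does not use, the OT-2 arrays shared 77 called rises with the knockout, where independent lists give 37, and 70 called falls, where they give 24.8. They included Btla (2.68 and 1.85), P2rx7 (2.13 and 1.39), Il18r1 (1.34 and 1.32), Slc6a19 (-1.96 and -1.78) and Sema7a (-1.33 and -1.56), given as the change in the knockout and in OT-2. Nrp1, which codes for a semaphorin receptor, went opposite ways (-1.27 and 1.24). Across all genes r was 0.05 (rho = -0.05), and across named genes 0.32.

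**Figure D3:**
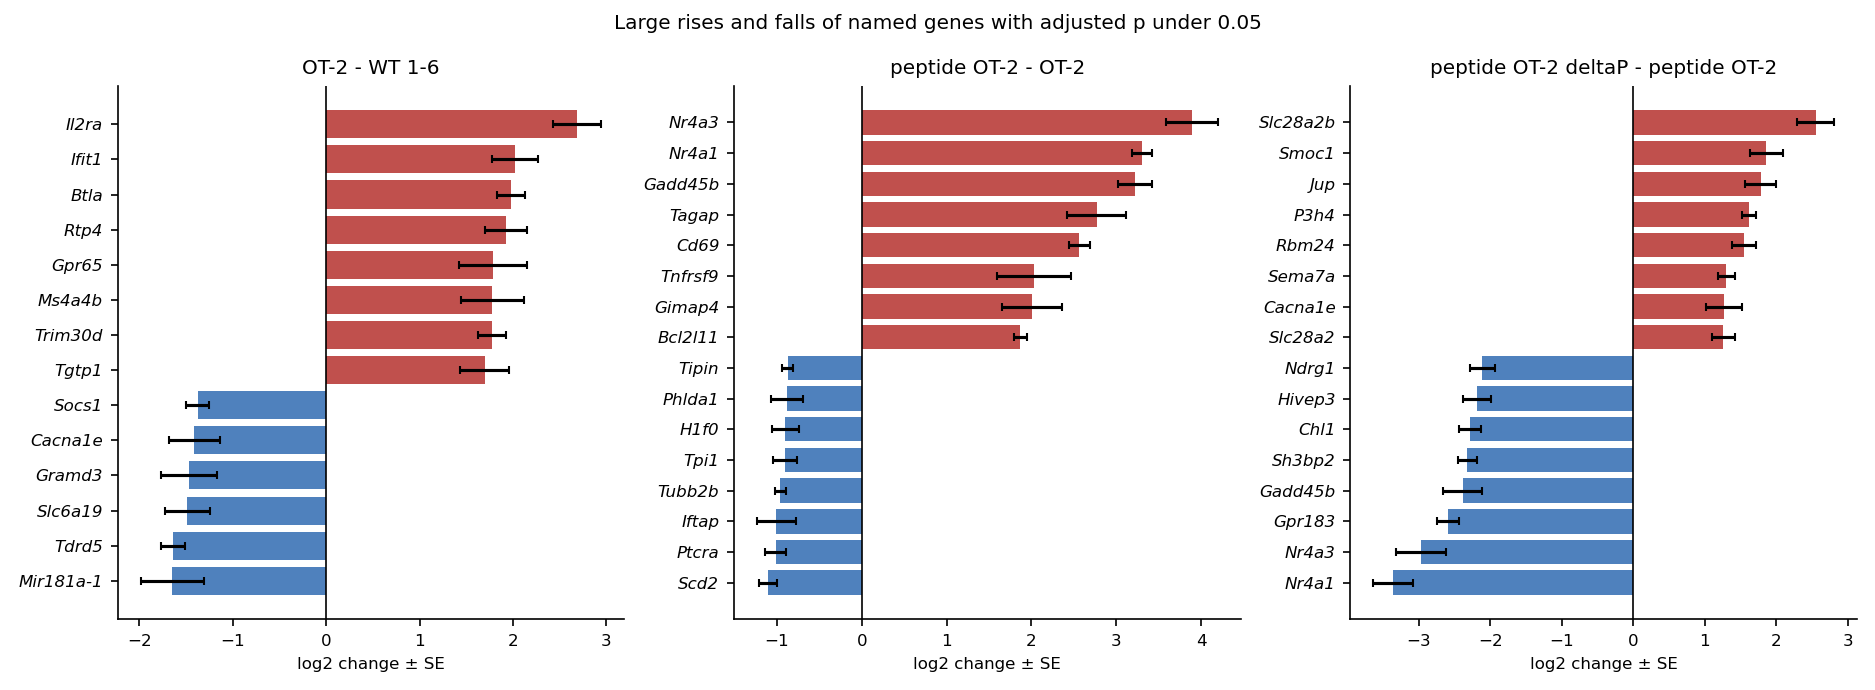
Bars give the log2 change and its SE for named genes with large rises and falls in the OT-2, peptide and deltaP comparisons (3 arrays per group, 6 for wild type). Nr4a1, Nr4a3 and Gadd45b have bars to the right in the peptide panel and to the left in the deltaP panel.

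Agonist peptide, which per the design text addresses negative selection, raised receptor-response genes in OT-2 thymocytes. Nr4a1, an orphan nuclear receptor gene induced by receptor signals, rose by 3.30 ± 0.12 (adjusted p = 3.00e-04, n = 3 and 3), and Nr4a3 by 3.89 ± 0.31 (adjusted p = 0.0044). Bcl2l11, the gene of the pro-apoptotic protein Bim, rose by 1.87 ± 0.07 (adjusted p = 3.32e-04), and Gadd45b, a stress-response gene, by 3.22 ± 0.21 (adjusted p = 0.0022). Cd69 rose by 2.57 ± 0.12 (adjusted p = 8.14e-04). Tagap (2.77), Tnfrsf9 (2.03) and Gimap4 (2.01) were the other large rises, with Tnfrsf9 passing in 3 and Gimap4 in 4 of the 6 fits that left out an array. The falls were smaller: Scd2 (-1.10), Ptcra (-1.01), Iftap (-1.01), Tubb2b (-0.96), Tpi1 (-0.90), H1f0 (-0.90), Phlda1 (-0.88) and Tipin (-0.87). Scd2 codes for a fatty acid desaturase and Tipin for a replication fork protein. Of these falls, Scd2, Ptcra, Tubb2b and Tipin passed whichever array was left out. Among the 56 changed genes selected for naming, 27 did so and passed under both other scalings. In the other 4 of the 8 falls the call was lost without OT-2 replicate 1.

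Of 22 T cell receptor activation genes, 16 rose and 6 did not pass, 18 rose when adjusted over the list alone, and the median was 0.98 (adjusted p = 1.14e-11, adjusted p = 0.0377 with an estimated correlation). Of the list calls in this comparison, this one alone held with an estimated correlation. Egr2 (1.47), a transcription factor gene, was among the rises. Of 14 NF-kB targets, 12 rose and 2 did not pass, 13 rose when adjusted over the list alone, with a median of 0.98 (adjusted p = 3.63e-11, adjusted p = 0.286 with an estimated correlation). They included Icam1 (1.29), an adhesion receptor gene, Tnfaip3 (1.06), which codes for a brake on NF-kB, Relb (1.52) and Birc3 (0.81). Among 6 pro-apoptotic genes, Bcl2l11, Gadd45b and Bbc3 (0.44), the gene of Puma, rose, and Tnfsf10 (-0.48), the gene of TRAIL, fell and 2 did not pass (median 0.41, adjusted p = 0.0293, adjusted p = 0.286 with an estimated correlation; 3 rose and 2 fell when adjusted over the list alone). Anti-apoptotic genes rose in the same arrays in 3 of 7, namely Birc3, Bcl2 (0.78) and Bcl2a1d (1.33) (median 0.35, adjusted p = 0.0121, adjusted p = 0.317 with an estimated correlation; 4 when adjusted over the list alone). The glucocorticoid-responsive genes Per1 (1.05), Tsc22d3 (1.04) and Pik3ip1 (0.66) rose of 4 (median 0.85, adjusted p = 0.0063, adjusted p = 0.317 with an estimated correlation; 3 when adjusted over the list alone). Of 9 regulatory and agonist-selected genes 5 rose, among them Pdcd1 (1.05), Tnfrsf4 (1.01) and Ikzf2 (0.52) (median 0.52, adjusted p = 0.008, adjusted p = 0.337 with an estimated correlation; 5 when adjusted over the list alone). Of 7 MAPK feedback regulators the phosphatase genes Dusp2 (1.25) and Dusp5 (1.03) rose (median 0.25, adjusted p = 0.0076, adjusted p = 0.317 with an estimated correlation; 2 when adjusted over the list alone).

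The lists of cholesterol synthesis and cell cycle genes were lower after peptide. Of 11 cholesterol synthesis genes 10 fell and 1 did not pass, 11 fell when adjusted over the list alone, with Msmo1 (-0.82), Insig1 (-0.77), Fdft1 (-0.65) and Fdps (-0.57) among them and a median of -0.57 (adjusted p = 5.05e-05, adjusted p = 0.286 with an estimated correlation). Of 23 cell cycle genes 11 fell and 12 did not pass, 16 fell when adjusted over the list alone, with a median of -0.41 (adjusted p = 3.89e-04, adjusted p = 0.595 with an estimated correlation), and Ccne2 (-0.72) and the mitotic kinase gene Cdk1 (-0.69) were among them. Of 8 pre-selection genes Ptcra and Endou (-0.58) fell, 6 did not pass and 7 fell when adjusted over the list alone (median -0.45, adjusted p = 0.0141, adjusted p = 0.286 with an estimated correlation). Jak3 (0.75), Stat6 (0.46), Socs1 (0.47) and Il21r (0.32) rose of 13 cytokine receptor and JAK-STAT genes, Ifngr1 (-0.41) fell and 8 did not pass (median 0.32, adjusted p = 0.0121, adjusted p = 0.317 with an estimated correlation; 7 when adjusted over the list alone). The maturation list (median 0.26, adjusted p = 0.0121, adjusted p = 0.595 with an estimated correlation) had 2 rises, Cd69 and Bcl2, and 1 fall, Ms4a4b (-0.32), among 19, with 4 rises when adjusted over the list alone. The interferon list (median 0.22, adjusted p = 0.0448, adjusted p = 0.662 with an estimated correlation) had 1 rise among 14, Gbp3 (0.82), and 0 when adjusted over the list alone. Ms4a4b stood at 0.06 once the difference between the wild-type sets was removed. The calls of the pro-apoptotic (0.0589), pre-selection (0.0731) and interferon (0.0731) lists were lost after quantile normalization. Without peptide replicate 2 the pro-apoptotic list reached 0.0877, and the interferon list was lost without peptide replicates 2 (0.0872) or 3 (0.141) or OT-2 replicate 3 (0.285). Over the alternatives the adjusted p ranged from 0.0138 to 0.0877 for the pro-apoptotic, from 0.0095 to 0.0731 for the pre-selection and from 0.0083 to 0.285 for the interferon list. After that normalization 6 cell cycle and 1 pre-selection genes fell, and 7 cytokine, 4 maturation and 3 interferon genes rose. The 7 lists that did not pass had adjusted p from 0.3508 to 0.9958. The comparison gave 5629 changed genes, 2705 higher and 2924 lower, and a split of 2043 and 4769 with arrays centred on their medians. With 1 array left out the count was 2273 without peptide replicate 1, and 745, 1540 and 2114 without OT-2 replicates 1, 2 and 3 in turn. With a threshold of 1.5-fold added the count was 932.

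**Figure D4:**
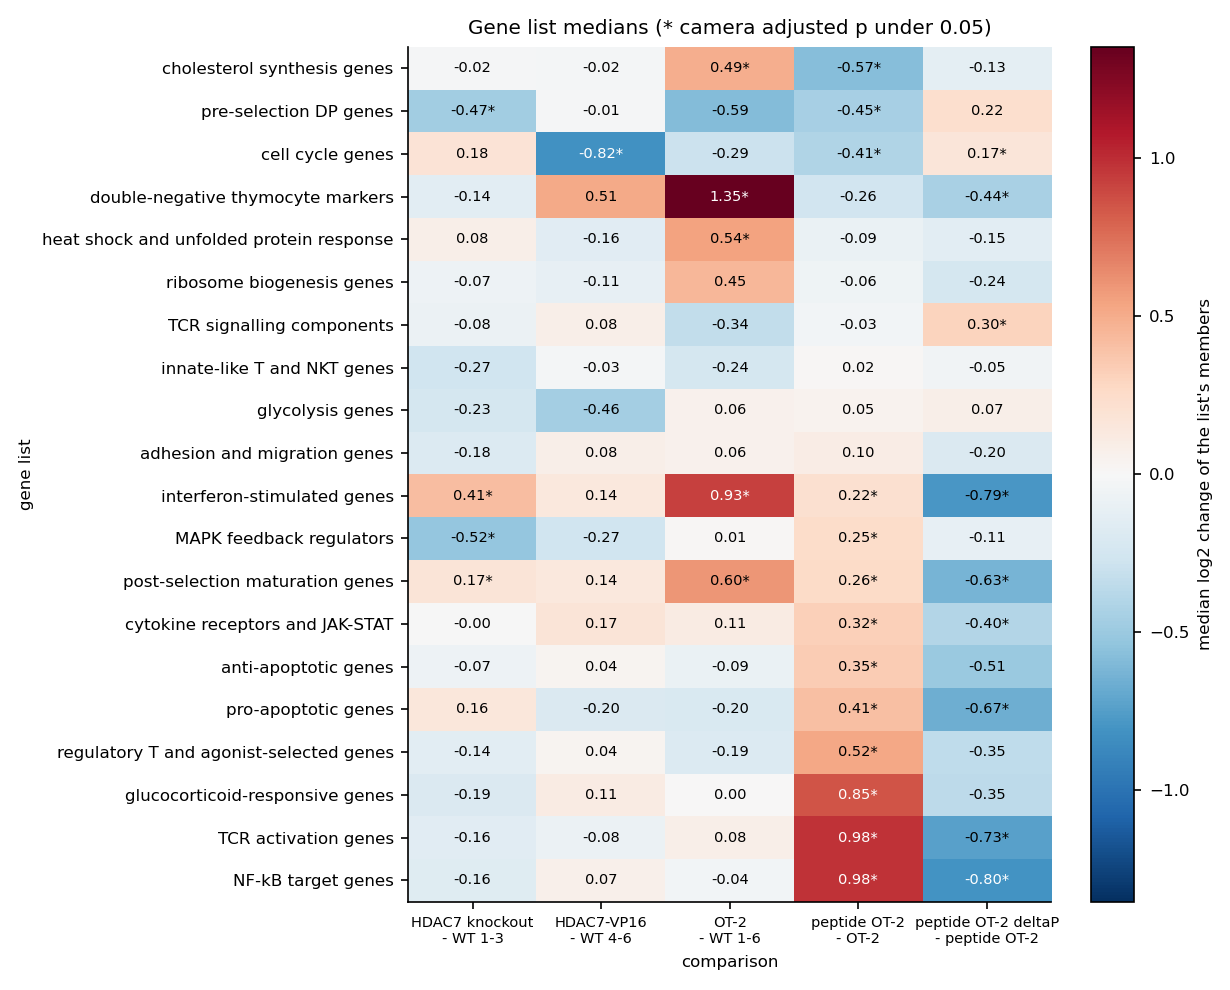
Each cell gives the median log2 change over the named members of a gene list (vertical axis) in 1 comparison (horizontal axis), with colour for its size, and a star marks a camera adjusted p under 0.05. The NF-kB target genes stand at 0.98 after peptide and at -0.80 with deltaP.

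The deltaP comparison, for which the design text gives no purpose, sets peptide-injected OT-2 arrays that the titles give as deltaP against those without it. The genotype label of these arrays carries OT-2 alone, and their Hdac7 values were 10.20, 10.44 and 10.56, so the transgene rests on the titles. In these arrays 117 of the 120 genes that rose at least 2-fold after peptide stood lower, and 8 of the 9 that fell as far stood higher. The same peptide arrays served to pick these genes and are the control here. Part of this reversal therefore arises without any effect of deltaP, and the counts to be had without an effect are not given. The median over all genes tested was -0.10 as deposited, 0.01 after quantile normalization and 0.09 with arrays centred on their medians. Nr4a1 changed by -3.36 ± 0.28 against peptide-injected OT-2 (adjusted p = 0.0028, n = 3 and 3), which is -3.26 relative to the median as deposited. Gpr183, the gene of a receptor for oxysterols, changed by -2.59 ± 0.16 (adjusted p = 0.0012; -2.49 relative to the median), and Gadd45b by -2.39 ± 0.27 (adjusted p = 0.0061; -2.29). Bcl2l11 changed by -1.10 ± 0.15 (adjusted p = 0.0075). Smoc1, which codes for a secreted calcium-binding protein, rose by 1.86 ± 0.23 (adjusted p = 0.0067; 1.96). The other large falls were Nr4a3 (-2.97), Sh3bp2 (-2.32), Chl1 (-2.28), Hivep3 (-2.19) and Ndrg1 (-2.11), and the other large rises were Slc28a2b (2.55), Jup (1.78), P3h4 (1.62), Rbm24 (1.55), Sema7a (1.30), Cacna1e (1.26) and Slc28a2 (1.26), all as deposited. Except Cacna1e, which was lost without deltaP replicates 2 or 3, these genes passed whichever array was left out. The comparison gave 4348 changed genes, 612 higher and 3736 lower, against 439 and 404 after quantile normalization and 3634 and 1016 with arrays centred on their medians. In genes above the median level the split was 181 and 403. With 1 array left out the count was 2289, 1228 and 1091 without deltaP replicates 1, 2 and 3 in turn, and 1632 and 2364 without peptide replicates 1 and 2 in turn.

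Of 22 T cell receptor activation genes 13 fell and 9 did not pass, 15 fell when adjusted over the list alone, all 22 were lower, and the median was -0.73 (adjusted p = 2.15e-08, adjusted p = 0.542 with an estimated correlation). Cd69 (-1.37) and Egr2 (-0.86) were among the falls. Of 14 NF-kB targets 10 fell and 4 did not pass, 14 fell when adjusted over the list alone, with Nfkb2 (-1.39), Relb (-1.24), Icam1 (-0.98) and Tnfaip3 (-0.83) among them and a median of -0.80 (adjusted p = 2.15e-08, adjusted p = 0.542 with an estimated correlation). Of 14 interferon-stimulated genes 9 fell and 5 did not pass, 12 fell when adjusted over the list alone, among them the factor gene Irf9 (-0.83), with a median of -0.79 (adjusted p = 2.64e-06, adjusted p = 0.542 with an estimated correlation). Of 19 maturation genes 9 fell and 1 rose, 12 and 2 when adjusted over the list alone, with a median of -0.63 (adjusted p = 6.86e-04, adjusted p = 0.542 with an estimated correlation). Itm2a (-1.39) and Gata3 (-1.20) were among the falls. Of 6 pro-apoptotic genes, Bcl2l11, Gadd45b, Bbc3 (-0.80) and Tnfsf10 (-0.53) fell, the same 4 when adjusted over the list alone, with a median of -0.67 (adjusted p = 0.0177, adjusted p = 0.542 with an estimated correlation). Of 13 cytokine receptor and JAK-STAT genes 4 fell and 1 rose (median -0.40, adjusted p = 0.0445, adjusted p = 0.542 with an estimated correlation; 6 fell when adjusted over the list alone), Jak3 (-0.80) among the falls. The double-negative markers (median -0.44, adjusted p = 0.0445, adjusted p = 0.542 with an estimated correlation) had 2 falls among 5, Hes1 and Dtx1, with the same 2 when adjusted over the list alone. The cell cycle list (median 0.17, adjusted p = 0.0153, adjusted p = 0.643 with an estimated correlation) had 1 rise, Ccnb2 (0.39), which passed in 0 of the 6 fits that left out an array, and 0 when adjusted over the list alone. The list of T cell receptor signalling components (median 0.30, adjusted p = 0.0467, adjusted p = 0.542 with an estimated correlation) had 3 rises among 9, Themis (0.65), Plcg1 (0.45) and Cd4 (0.64), and 4 when adjusted over the list alone. Of these, Themis passed in 3, Plcg1 in 1 and Cd4 in 2 of the 6 such fits. Those last 2 lists did not pass after quantile normalization (0.112 and 0.17), in ranges from 0.0017 to 0.145 and from 0.0276 to 0.17 over the alternatives. After that normalization 5 interferon, 2 cytokine and 1 double-negative genes fell, and 0 signalling, cell cycle, cytokine and maturation genes rose. The 11 lists that did not pass had adjusted p from 0.0580 to 0.8600.

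Some of these list calls were lost without single arrays or with the difference between the wild-type sets removed. With it removed the cell cycle and double-negative calls were lost (0.0675 each). The cell cycle call was lost without deltaP replicate 1 (0.0782) or peptide replicate 1 (0.145), and the signalling call without deltaP replicates 2 (0.0756) or 3 (0.0519) or peptide replicates 2 (0.103) or 3 (0.0689). The cytokine call was lost without deltaP replicates 1 (0.0502) or 2 (0.0756) or peptide replicates 2 (0.103) or 3 (0.051), and the double-negative call without deltaP replicate 2 (0.0655) or peptide replicate 3 (0.106). The adjusted p of these last 2 lists ranged from 0.0123 to 0.103 and from 0.0241 to 0.106 over the alternatives. Of the 120 genes that rose at least 2-fold after peptide, 117 were lower with deltaP and 79 fell. Their median was 1.16 for peptide against OT-2, -1.0 for deltaP against peptide and 0.28 for deltaP against OT-2 without peptide. Against untreated OT-2, 42 of them rose with deltaP, Cd69 (1.20), Tagap (1.32) and Nr4a3 (0.91) among them, whereas Nr4a1 stood at -0.06. The same OT-2 arrays had served to pick these genes: over 50 simulations with no response left and genes picked alike, the median was 0.06 to 0.16, and at most 23 genes of 226 on average were past the threshold. The data gave 120 genes where the simulations gave 226, so they do not match the data closely and are a rough guide. OT-2 and deltaP arrays lie in different blocks, so a response left over and a block difference cannot be told apart. Because both comparisons hold the same peptide arrays, a negative relation between them arises without any effect: r was -0.60 where unchanged groups simulated on the same arrays gave -0.50, and the covariance was -0.0523 against -0.0111. The simulated groups held no block difference, whereas both comparisons cross blocks. Their changes correlated with the wild-type set difference at r = -0.52 for peptide and 0.39 for deltaP. The larger covariance in the data therefore cannot be told apart from a block difference. DeltaP against untreated OT-2 gave 5489 changed genes, 1019 higher and 4470 lower with a median over all genes of -0.11, and 1466 and 1488 after quantile normalization. It gave 2059 and 1171 with arrays centred on their medians.

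The knockout and deltaP comparisons share no array, and genes called in one tended to lie the other way in the other. Of the 127 genes that rose in the knockout, 120 were lower with deltaP and 71 fell, with a median of -0.56 (adjusted p = 7.26e-18, adjusted p = 0.132 with an estimated correlation). Of the 105 that fell in the knockout, 81 were higher with deltaP and 42 rose, with a median of 0.33 (adjusted p = 1.90e-21, adjusted p = 0.132 with an estimated correlation). Independent lists would give 16.4 and 2.22 such opposite calls. After quantile normalization 47 of the former fell and 22 of the latter rose, with medians of -0.54 and 0.34. The opposite calls as deposited included Btla (2.68 and -2.09), Chl1 (2.34 and -2.28), Hivep3 (1.55 and -2.19), Smoc1 (-2.14 and 1.86), Jup (-2.33 and 1.78) and Slc28a2b (-1.71 and 2.55), given as the change in the knockout and with deltaP. The changes correlated at r = -0.10 (rho = 0.01) across all genes and at r = -0.45 across the named ones.

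**Figure D5:**
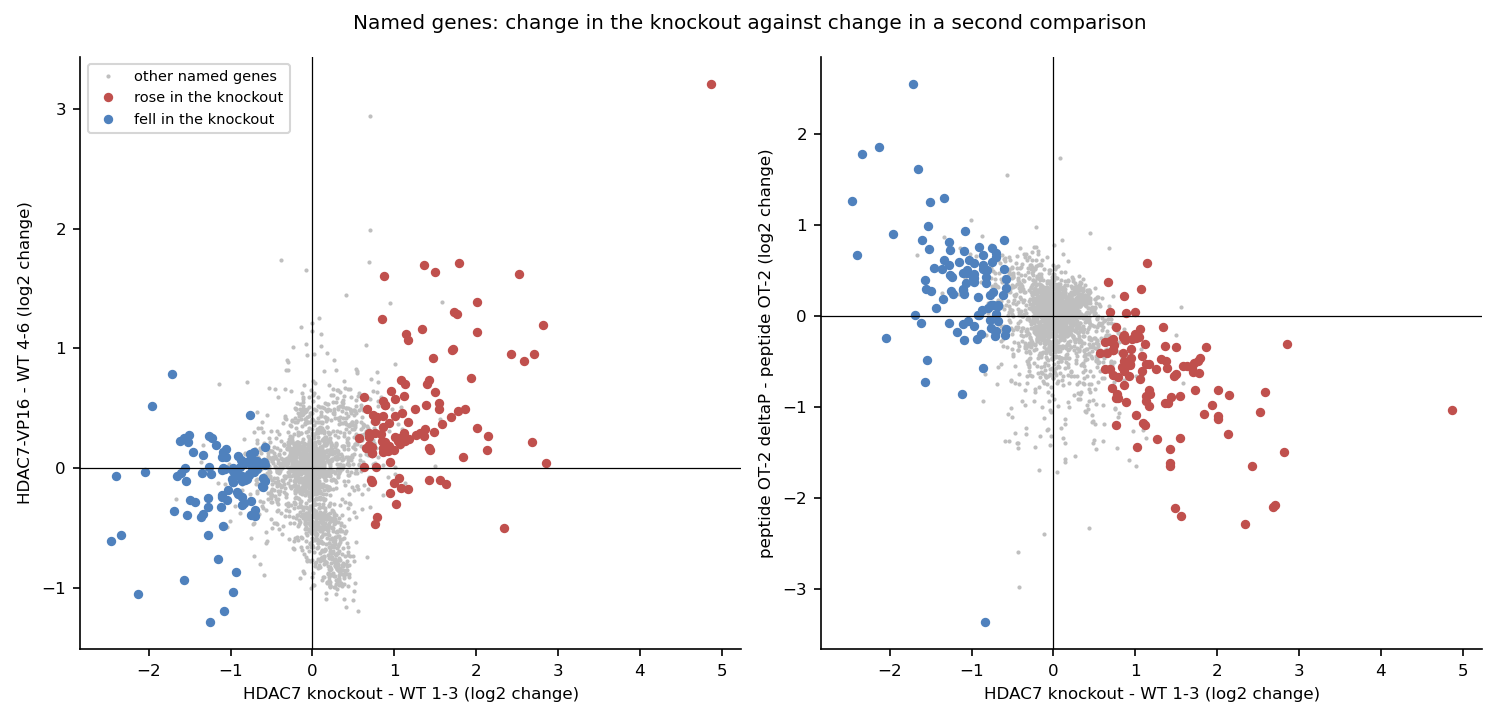
Each point is 1 of 2121 named genes, with its log2 change in the knockout on the horizontal axis and in the VP16 (left) or deltaP (right) comparison on the vertical axis; red points rose and blue points fell in the knockout. Of the 107 named genes that rose in the knockout, 93 lie above 0 on the left and 100 below 0 on the right.

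Correlations across genes were also computed for the other pairs. VP16 and OT-2 against wild-type arrays 1 to 3 shared 80 called rises, where independent lists give 29.6 (r = -0.04, rho = -0.11 across all genes), and 32 called falls, where they give 25.7. The called falls in VP16 included 40 that rose in OT-2, where they give 31.3, and 15 of its rises fell there, where they give 24.3. VP16 and peptide shared 76 called falls, where they give 21.3 (r = 0.22, rho = 0.21), but 12 called rises, where they give 18.7. Of the genes called in both, 35 rose in VP16 and fell after peptide, where they give 20.2, and 9 went the other way, where they give 19.7. The knockout and peptide changes had r = -0.05, rho = -0.06, and the VP16 and deltaP changes r = -0.21, rho = -0.20. Of 127 knockout rises, 84 were higher and 43 lower after peptide (camera adjusted p = 0.0025, 0.286 with an estimated correlation). The knockout falls did not pass there (camera adjusted p = 0.47). Of 200 VP16 rises, 46 were higher and 154 lower with deltaP (median -0.27, camera adjusted p = 0.0022, 0.257 with an estimated correlation). Of 211 VP16 falls, 137 were higher and 74 lower (median 0.11, camera adjusted p = 6.23e-10, 0.171 with an estimated correlation). OT-2 and peptide share the OT-2 arrays and had r = -0.28, rho = -0.28, where unchanged groups simulated on the same arrays gave r = -0.57. The covariance was -0.0247 against -0.0110 simulated, so it was larger in size although r was smaller. Peptide and deltaP against OT-2 had r = 0.48, rho = 0.47, where these groups gave r = 0.50, with a covariance of 0.0384 against 0.0109. The simulated groups held no block difference, so the larger covariances cannot be told apart from one.

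Other lists passed in no comparison. The medians of 9 adhesion and migration genes were -0.18 in the knockout (adjusted p = 0.494, adjusted p = 0.84 with an estimated correlation), 0.08 in VP16, 0.06 in OT-2, 0.10 after peptide and -0.20 with deltaP, where Itga6 (0.43) rose and Gpr183 (-2.59) and Ccr4 fell. Those of 4 ribosome biogenesis genes were -0.07, -0.11, 0.45 (adjusted p = 0.177, adjusted p = 0.969 with an estimated correlation), -0.06 and -0.24 in the same order, with Npm1 (-0.43), a nucleolar protein gene, the single member that passed, after peptide. Npm1 passed in 1 of the 6 fits that left out an array, and not after quantile normalization (-0.26, adjusted p = 0.144) or with the wild-type set difference removed (-0.11, adjusted p = 0.511). Those of 3 glycolysis genes were -0.23, -0.46 (adjusted p = 0.139, adjusted p = 0.869 with an estimated correlation), 0.06, 0.05 and 0.07, and the enzyme genes Tpi1 (-0.66) and Eno1 (-0.46; -0.35, adjusted p = 0.0626 after quantile normalization) fell in VP16. Those of 4 innate-like T cell genes were -0.27, -0.03, -0.24, 0.02 and -0.05 (adjusted p = 0.561, adjusted p = 0.672 with an estimated correlation), with Gzma risen in VP16, Slamf1 (-0.68) fallen in OT-2 and Slamf6 (0.66), a signalling lymphocyte receptor gene, risen with deltaP. Lists with fewer than 3 named members were not tested, namely those of B cells (Cd79b and Blk), macrophages and dendritic cells (Itgam), thymic epithelium (Cldn4), erythroid cells (Tfrc) and stroma and endothelium (Pdgfrb). Of these, Itgam rose in the knockout, Blk rose and Tfrc fell (-0.41; -0.37, adjusted p = 0.0527 after quantile normalization) in VP16, and Cd79b (-0.54) and Cldn4 (-0.84) fell after peptide.

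In some lists that did not pass, the median, the mean and the direction of the test differed in sign. The test sets a list's moderated t values against those of the other named genes and not against 0, and the median change of all named genes was 0.01 in the knockout, -0.13 in OT-2, -0.10 after peptide and 0.02 with deltaP. In the knockout the median and mean were 0.16 and -0.06 for pro-apoptotic, -0.27 and 0.05 for innate-like, -0.14 and 0.05 for regulatory and 0.08 and 0.01 for heat shock genes, and the test pointed down in each. In VP16 they were 0.04 and -0.04 for anti-apoptotic genes with a test that pointed down, and -0.03 and 0.21 for innate-like and -0.01 and 0.01 for pre-selection genes with a test that pointed up. In OT-2 they were 0.01 and -0.03 for MAPK feedback, -0.20 and -0.06 for pro-apoptotic, 0.00 and -0.04 for glucocorticoid-responsive and -0.19 and 0.24 for regulatory genes, and the test pointed up. After peptide they were 0.05 and -0.26 for glycolysis with a test that pointed down, and -0.03 and -0.03 for T cell receptor signalling genes with a test that pointed up. With deltaP they were -0.05 and -0.05 for innate-like genes with a test that pointed up.

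Further calls of named genes ended under another setting; changes in brackets run from the value as deposited to that under the setting. After quantile normalization Endou (-0.58 ± 0.11 to -0.41 ± 0.12) and Ms4a4b (-0.32 ± 0.09 to -0.26 ± 0.09) did not pass after peptide, and Itga6 (0.43 ± 0.11 to 0.40 ± 0.12), Dtx1 (-0.65 ± 0.16 to -0.67 ± 0.15) and Tnfsf10 (-0.53 ± 0.09 to -0.42 ± 0.09) did not pass with deltaP. Of these, Endou and Tnfsf10 moved by more than the SE as deposited. The VP16 changes of Bub1, Ccne2, Depdc1a, Dtx1 and Il2ra, whose calls ended there too, moved by less. With arrays centred on their medians Ccr4, Fdft1, Gpr65, Hspa5, Mvd, Nr4a1 and Slamf1 were lost in OT-2 and Il21r after peptide, all with a change that moved by less than its SE, and Dtx1 (-0.65 to -0.45) with deltaP. With the wild-type set difference removed, which was chosen after the data were seen, Bub1 (-0.99 ± 0.18 to -0.95 ± 0.18) and Ccne2 (-0.91 ± 0.16 to -0.82 ± 0.15) in VP16, Iftap (-1.01 ± 0.23 to -0.93 ± 0.22) and Phlda1 (-0.88 ± 0.19 to -0.81 ± 0.19) after peptide and Cd4 (0.64 ± 0.18 to 0.58 ± 0.18) with deltaP passed the threshold no longer, but moved by less than their SE. The loss of these calls therefore does not show that they depend on that difference. Cdk1 (-0.69 ± 0.11 to -0.46 ± 0.10), Cd79b (-0.54 ± 0.08 to -0.27 ± 0.08), Cldn4 (-0.84 ± 0.14 to -0.50 ± 0.14), Endou (-0.58 ± 0.11 to -0.30 ± 0.12), H1f0 (-0.90 ± 0.16 to -0.68 ± 0.16) and Tpi1 (-0.90 ± 0.14 to -0.63 ± 0.14) after peptide and Ccnb2 (0.39 ± 0.10 to 0.22 ± 0.10) with deltaP were lost with changes that shrank by more than their SE. Of the fits that left out an array, at most 2 passed for Cenpk, Depdc1a, Bub1, Ccne2, Gata3, Itgb7, Ifngr1, Il2ra, Smoc1, Tpi1, Eno1, Tfrc and Cd52 in VP16, for Fdft1 and Slamf1 in OT-2, for Bcl2a1d, Gbp3, Iftap, Phlda1, Il21r, Pik3ip1, Tsc22d3 and Ms4a4b after peptide, and for Dtx1 and Itga6 with deltaP. Among the 57 changed genes selected for naming with deltaP, 35 passed whichever array was left out and under both other scalings.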

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

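The test of the difference between the effects below was planned, whereas the comparison with regrouped arrays was chosen after the result was seen. In the 6 wild-type arrays 60 values were tested by Dixon's ratio, namely those of named genes and the median and SD of the arrays. In 5 of them, all named genes, 1 array lay far from the others and the ratio passed the 95% critical value. Chance flags about 1 in 20 groups. Mvd had a ratio of 0.706, with 1 array at 7.22 and the others from 7.38 to 7.45. Pdgfrb had 0.703, with 5.96 against 6.29 to 6.43. Pim1 had 0.639, with 9.56 against 10.01 to 10.26. Zbtb7b had 0.6253, with 6.24 above 6.11 to 6.16. Arpp21 had 0.756, with 11.08 against 11.38 to 11.48. No biological explanation was tested for these arrays.

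The effect of VP16 differed from that of the knockout in 231 genes by a test of the difference itself. Of these, 52 had risen and 70 had fallen in the knockout, 38 had risen and 20 had fallen in VP16, and 65 were called in neither. Of 100 regroupings of the arrays within each wild-type set, the real one included, 1 gave as many genes and the highest other gave 168. A regrouping breaks the knockout and the VP16 effect at once, so it cannot test whether these effects are equal. Chance was therefore not excluded for a difference between them. With the replicate number as a block in the knockout and wild-type arrays that it pairs, an alternative chosen after the result was seen, the count was 633. Regroupings do not test equal effects here either: of 80 that swapped whole pairs or regrouped the VP16 set, the real one included, 2 gave as many. The other of the 2, with 784, exchanged VP16 with its wild-type arrays and so tested the sum of the effects in place of their difference. The 18 that kept the knockout arrays and mixed the VP16 set gave 100 to 211, so part of the count follows from the knockout effect alone, and those that swapped knockout pairs gave at most 3. Each effect was measured against wild-type arrays of its own block. With 1 shared control the control cancels, so VP16 arrays were set directly against knockout arrays of another block. The count was then 15803, with the difference between the blocks in the contrast.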

How the results depend on the processing

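Removing the difference between the wild-type sets, the wild-type sets as 2 groups, the replicate block for the difference between effects, and the other scalings of deltaP against OT-2 and of the wild-type sets were chosen after the results were seen; the rest was planned. Among 227 called named genes, 3046 of 3662 values under an alternative kept direction and call, 615 kept the direction without passing, and 1 changed sign (Ms4a4b after peptide, 0.057 with the wild-type set difference removed). Among 83 named genes not called, 1198 of 1388 values kept direction and call, 161 passed and 29 changed sign. Unless stated, the cause of a change was not tested.

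Counts moved by more than 1.5 times as follows. With all 21 arrays in 1 fit they were 788 for the knockout, 661 for VP16, 2901 for OT-2 and 6604 for deltaP. Quantile normalization of all 21 arrays gave 188 for VP16, 1434 for OT-2, 3748 for peptide, 843 for deltaP, 2954 for deltaP against OT-2 and 10586 between the wild-type sets. Of the calls made as deposited, 229 of 232 in the knockout, 181 of 411 in VP16, 521 of 667 in OT-2, 2937 of 5629 after peptide and 669 of 4348 with deltaP were also made after it, with 0 of opposite sign. Of the genes that rose in the knockout 47 fell with deltaP after it (71 as deposited), and of those that fell 22 rose (42 as deposited; 25 with the wild-type set difference removed). Arrays centred on their medians gave 3230 for deltaP against OT-2. Genes above the median level, 14460 tested in each case, gave 1724 for VP16, 3187 for peptide, 584 for deltaP and 460 for the difference between VP16 and knockout effects. Adding a threshold of 1.5-fold, which can only lower a count, gave 182 for VP16, 932 for peptide and 1167 for deltaP. An intensity trend with robust fitting gave 1619 for VP16, and array weights gave 1080 for VP16 and 14688 for OT-2. Every row of the value table gave 139 for the knockout, 32 for VP16 and 1687 for deltaP. With the replicate block the counts were 6568 for OT-2 with wild-type replicates 1 to 3, 3328 for peptide and 2801 for deltaP, where numbers did not pair the arrays. For OT-2 the control changed too, and the same control without the block gave 7805.

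All 6 wild-type arrays as control gave 34 for VP16. The difference between effects gave 15803 with VP16 arrays set directly against knockout arrays, as a shared control cancels. It gave 633 with a replicate block for the knockout pairs. OT-2 gave 7805 against wild-type replicates 1 to 3, 15256 against replicates 4 to 6 and 7351 with the wild-type sets as 2 groups. Removing the wild-type set difference gave 9268 for OT-2, 1297 for peptide and 2252 for deltaP, and 667 of 667, 1114 of 5629 and 1960 of 4348 of the calls as deposited were among these. For OT-2 this removal takes the difference between the wild-type sets out of its own control by construction. The higher OT-2 count and its kept calls are therefore not evidence that those calls are robust. Leaving out 1 array gave 107 to 155 for the knockout, 35 to 790 for VP16, 51 to 671 for OT-2, 745 to 4651 for peptide, 1091 to 3639 for deltaP and 93 to 399 for the difference between effects, with the arrays named in the report. For most of these fits fewer arrays lower the power, but the higher counts do not follow from it.

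Of the lists, 0 passed with an estimated correlation in the knockout, VP16, OT-2 and deltaP comparisons and 1 after peptide, where the correlation estimated from 3 arrays per group is the part that changed. VP16 had 4 lists by fry and 2 after quantile normalization. The 4 were MAPK feedback, glycolysis, heat shock and innate-like genes, and the cell cycle call was lost by fry (0.0706). Fry also lost the interferon and maturation calls in the knockout, heat shock in OT-2, interferon, maturation and regulatory genes after peptide, and the signalling, cell cycle and double-negative calls with deltaP. Leaving out 1 array gave 2 to 6 lists for the knockout and 1 to 2 for VP16.

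With all 6 wild-type arrays as control, where the block difference enters, correlations across genes were -0.51 for knockout with VP16 and 0.063 for VP16 with OT-2, pairs that then share controls and for which unchanged groups simulated on the same arrays gave 0.33 each. They were 0.40 for knockout with peptide, -0.33 for VP16 with peptide, -0.39 for knockout with deltaP and 0.22 for VP16 with deltaP. With the wild-type set difference removed they were 0.19 for knockout with OT-2, 0.15 for VP16 with OT-2, 0.12 for VP16 with peptide and -0.14 for VP16 with deltaP. In genes above the median level they were -0.27 for knockout with deltaP, -0.45 for peptide with deltaP and 0.57 for peptide with deltaP against OT-2.

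Genes not called changed sign in these cases. With all 6 wild-type arrays as control, Ccnb1 (-0.16), Hspa5 (-0.11), Blk (0.10), Tfrc (-0.11) and Pdgfrb (0.014) did so in the knockout, and Bcl2a1d (0.28), Npm1 (0.10) and Cldn4 (0.036) in VP16. In OT-2, Tpi1 (-0.011), Cd79b (-0.021) and Cldn4 (-0.024) did so with array weights, and Tpi1 (-0.10), Cd79b (-0.082) and Cldn4 (-0.15) against wild-type replicates 4 to 6. After peptide, Hdac7 stood at 0.10 after quantile normalization and Hdac5 at -0.0196 with arrays centred on their medians, and with that centring Hdac7 (0.033), Cd79b (0.09) and Cldn4 (0.12) changed sign with deltaP. Leaving out 1 array in turn, the ranges that crossed 0 were -0.17 to 0.0027 for Nolc1, -0.0137 to 0.23 for Tfrc and -0.15 to 0.027 for Pdgfrb in the knockout, -0.20 to 0.011 for Bcl2a1d in VP16, -0.26 to 0.051 for Hdac7 and -0.11 to 0.53 for Cd44 after peptide, and -0.29 to 0.017 for Hdac7, -0.0137 to 0.11 for Itgam and -0.14 to 0.028 for Cldn4 with deltaP.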

Other observations

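All the tests of explanations here were chosen after the results were seen. Genes picked for their peptide response were compared between the arrays with deltaP and peptide and untreated OT-2. Nr4a1 stood at -0.06, whereas Cd69 (1.20), which marks recent receptor signals, Tagap (1.32) and Nr4a3 (0.91) rose. The 9 genes that fell at least 2-fold after peptide had a median of -1.09 there, 0.65 for deltaP against peptide, and -0.51 for deltaP against untreated OT-2, where 5 fell. The OT-2 arrays served both to pick the genes and to compare them, and in 50 simulations with no response left the median of genes picked alike was -0.29 to -0.08. The simulations gave 35.5 such genes on average where the data gave 9, so they are a rough guide. OT-2 and deltaP lie in different column blocks, so a remaining response cannot be told apart from a block difference. Their arrays also lay apart in full on the unnamed probe sets 10606178, 10608001 and 10608138 given below.

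For the counts of changed genes, the same arrays were regrouped in every other way. The knockout (232, highest other 0), VP16 (411, 0), peptide (5629, 4), deltaP (4348, 0), deltaP against OT-2 (5489, 0) and wild-type set (16468, 0) comparisons have 10 splits each, of which 1, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. Splits of the knockout arrays that part the 3 replicate pairs (3 others) and those that part 1 pair (6) both had 0 as the highest count. For OT-2, 3 of 84 splits, the real one included, gave as many genes as the real 667. Arrays of different blocks cannot be exchanged freely, so this share does not exclude chance for an OT-2 effect. The split of wild-type arrays 4 to 6 against the other 6 gave 11860. That split follows the column blocks and points to a structure of the arrays larger than the OT-2 effect. The real split follows the blocks too, since the OT-2 arrays form a block of their own, so an OT-2 effect and a block difference cannot be told apart; with the wild-type sets as 2 groups the OT-2 comparison gave 7351.

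The 2 wild-type sets differed in 16468 genes. If the different distributions of the columns were the whole cause, few calls would stay after quantile normalization; 46.7% of them stayed with their sign, 7692 genes, which lies between the bounds set for this test and leaves the distributions open as a cause, though not as the whole cause of the calls that stayed. Probe-level normalization in separate groups, hybridization batch and the mice themselves stay open, and no value in the tables parts them. No biological difference between the sets is given by the labels.

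The peptide comparison sets a column block against another, and its changes correlated with the difference between the wild-type sets at r = -0.52 across genes. Of the 5208 calls outside the authors' deposited table, 90.5% lay opposite to that difference, as did 67.4% of the genes not called, which is consistent with separate normalization of the blocks for much of that part; 17.6% of these calls were also made once the difference was removed and 48.8% after quantile normalization. Of the 421 calls in that table, 75.3% lay opposite, too near the bound set for this test to decide, and 47.3% and 93.8% of them were also made under those settings. The calls that stayed once the difference was removed, 915 and 199, argue against the wild-type set difference as their whole cause, but the OT-2 arrays lie in a block other than either wild-type set. How much of both parts is response to the peptide stays open, since every peptide array lies in a block other than the OT-2 arrays.

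Genes called in the knockout lay the opposite way with deltaP, with a median of -0.56 for those that rose and 0.33 for those that fell. Quantile normalization cut the deltaP calls from 4348 to 843 but left these medians at -0.54 and 0.34, where 10000 random lists matched on level and on the wild-type set difference ranged from -0.07 to 0.08 and from -0.06 to 0.09. This argues against the different distributions of the columns as the whole cause. With the wild-type set difference removed, which left 2252 deltaP calls, the medians were -0.57 and 0.27, and the matched lists ranged from -0.15 to 0.00 and from -0.12 to 0.03, which argues against that difference as the whole cause. Single calls were fewer: of the genes that rose, 71 fell with deltaP as deposited, 47 after quantile normalization and 66 with the difference removed, and of those that fell 42, 22 and 25 rose. Against untreated OT-2 the genes that rose had a median of -0.40, outside the matched lists (-0.19 to -0.01), which argues against the peptide-injected arrays as the whole source. A difference of the deltaP column block that varies from gene to gene stays open, since 0 arrays of other groups lie in that block. A different share of more mature cells in the sorted gate stays open too: 15 of the 19 maturation genes were higher in the knockout and 16 were lower with deltaP, and no profile of mature cells is at hand to say how far each would move. An opposite effect of HDAC7 loss and of the deltaP transgene on the same genes may be a further explanation, as a hypothesis found and tested on the same data. The pattern was not seen in the knockout alone. Genes called in VP16 also lay the other way with deltaP, with medians of -0.27 for rises and 0.11 for falls.

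Some unnamed probe sets took either a high or a low value from array to array. Probe set 10606178 was high in 14 arrays, and 10608001 and 10608138 were high in 8. The latter were high wherever the first was low, and low wherever it was high except in VP16 replicate 2. Knockout replicate 3 and wild-type replicate 3 read 5.49 and 5.41 on the first, where the other arrays of their groups read from 10.93 to 12.20. All 3 deltaP arrays read low (4.64, 4.64 and 4.95), all 3 OT-2 arrays high (11.15, 11.24 and 11.37), and peptide replicate 1 (11.67) differed from replicates 2 (5.12) and 3 (5.25). VP16 replicate 2 read high on all 3 probe sets (10.84, 7.10 and 8.52). On these 3 probe sets the OT-2 and deltaP arrays thus lay apart in full, and the peptide arrays were mixed. What they measure is not given, and what trait of the mice or arrays they follow was not tested. Such a trait is unbalanced in the peptide comparison and in deltaP against peptide, where peptide replicate 1 differed from all deltaP arrays. It is also unbalanced in OT-2 against wild type, where wild-type replicate 3 differed from all OT-2 arrays. In deltaP against OT-2 it cannot be told apart from the group. Probe set 10582545 was high only in knockout replicate 2 (12.20) and peptide replicate 3 (12.63), and 10382846 only in knockout replicate 1 (10.64) and OT-2 replicate 3 (10.46).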
